A study of Homo sapiens with 3 samples.

How the data were processed

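Jurkat cells were grown in RPMI-1640 with 10% serum and harvested at a viability of 95% or more, per the labels. Total RNA was extracted with TRIzol and made into paired-end TruSeq libraries, per the labels' protocols, and sequenced on a HiSeq2000. The series text gives paired-end reads of 200 bases from each end and lengths of about 350 bases. CASAVA 1.8, Bowtie 0.12.7, TopHat 1.4.0, RSEM 1.1.20 and the genome build hg19 are named in the submitters' processing notes, with no role or order. The gene annotation, read filters and mapping settings are not given in the sources used here.

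The authors deposited TPM values divided by 1000000 for 23221 genes in 9 columns, 3 per sample, headed by the sample's number and by C01, C02 or C03. Per the file headers the number is a run, and the meaning of the C labels is not given in the sources used here. Values were multiplied by 1000000, so each column summed to between 999997 and 1000002 TPM. The 3 columns of a sample were averaged and counted as 1 replicate, which left n = 3. No column was left unmatched to a sample. TPM keeps no read depth, so counting limits for single genes are unknown. Estimates under 0.01 TPM, of which the table holds 350 above 0, were treated as near 0.

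The authors also deposited a TopHat junction list with a count of reads per junction, pooled over libraries that are not named in the sources used here. Intron positions were taken as the bases between both flanking blocks, counted from 1 on hg19. Counts were used as deposited, without normalization.

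No contrast exists between groups, so no p-value was computed. A gene was called detected at a mean of at least 1 TPM. The 10 marker lists and 20 pathway lists were fixed before the data were examined, and older symbols were matched through the NCBI RefSeq symbol table of GRCh38. A list was described by its members at or above 1 TPM and by the place of its median among the medians of 10000 random lists of the same size drawn from all listed genes. Shares carry 95% exact Clopper-Pearson intervals, which cover counting error only. Named genes were chosen by a rule fixed beforehand: the 10 highest, the 3 highest members of each list, members below 1 TPM where fewer than 6 were, otherwise the 2 lowest above 0, every T cell identity and leukaemia factor gene, INPP5D and INPPL1, the 10 junctions with the most reads with and without a match, the 10 genes with the most unmatched junctions of at least 5 reads, and 20 genes with known isoforms. Some genes that the rule names are left out of the text.

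The reference annotation, GENCODE release 29, is of GRCh38, another build than hg19, so no coordinates were compared or converted. A junction was matched when an annotated intron had the same chromosome, strand and length, and the chance share came from lengths shifted by 1 to 10 bases. Cassette exons were planned from the annotation. After seeing that the builds differ, they were instead inferred as stretches of at most 1000 bases between junctions, with no junction inside, both inclusion junctions, a skipping junction and at least 20 reads in all. Where several skipping junctions existed, the one with the most reads was used, and an alternative added later counted every junction that spans the exon and shares an outer end with its inclusion junctions. Inclusion was the mean of both inclusion junctions over that mean plus the skipping reads. Genes were assigned to exons and junctions only where the lengths of an intron, its neighbouring exon and the next intron equalled those of an annotated structure of 1 gene, a step also added after seeing the data. The comparison of TPM with junction reads used the same placement. The junctions with the most reads and the unmatched junctions, whose own length has no match, were assigned to the gene of junctions placed in this way that share a splice site with them, where these were of 1 gene.

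Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The list places, the length match and the structure match were tested on simulated data, and the inclusion shares were not. For the lists, 5.3% of 1000 random lists of 25 genes were placed above 9500 of 10000, and 100% of lists drawn from the highest 25% of 23221 genes were. For the length match, 49.3% of 10000 simulated long junctions were recovered as annotated after taking off chance, where 50% were planted. For the structure match, 100% of 5000 annotated structures and 0.02% of 5000 altered ones matched. In both match tests the planted lengths came from the annotation that was searched, so their recovery was fixed in advance. Neither test covers lengths that differ between the builds, and the share of real introns missed for that reason is unknown. Alternatives covered TPM floors of 0.1 and 5, rescaling without the 10 highest genes, other backgrounds and scales for lists, read and overhang filters for junctions, and leaving out each sample.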

Results

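The series measured messenger RNA of Jurkat cells (ATCC TIB-152), an immortalized human T-cell line derived from an acute T-cell leukaemia. Its title describes sample-specific protein databases built from RNA-seq to find splice junction peptides by mass spectrometry. There were 3 samples in 1 group and no contrast between conditions, so the data answer which genes and which splice junctions these cells express. Transcript levels in TPM (a measure of transcript number scaled to a fixed total) were listed for 23221 genes in every sample. Replicates 1, 2 and 3 carry the numbers 216, 245 and 236 in their titles. Levels of genes are given as mean ± SD over the 3 samples (n = 3). A list median is the median of its genes' means, given with the SD of the list medians of the 3 samples. The file header calls the sample numbers runs, so these errors measure only the spread between these samples, which may be technical. TPM values keep no read depth. A separate list held 280884 splice junctions with 47786098 reads in all and no division by sample, so it has no replicate error.

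EEF1A1, a translation elongation factor, had the highest level at 7314 ± 306 TPM. It was followed by GAPDH of glycolysis at 7109 ± 157 TPM and the actin-binding peptide gene TMSB4X at 6515 ± 323 TPM. The other genes among the 10 highest were ACTB at 5578 ± 43.4 TPM and the ribosomal protein genes RPS27, RPS18, RPS6, RPL41, RPS3A and RPL39. RPS27 stood at 6029 ± 1343 TPM and RPL39 at 4766 ± 648 TPM, while RPS3A at 4980 ± 30.7 TPM had a small SD. These 10 genes held 5.86% of all TPM. A mean of at least 1 TPM was reached by 12096 genes, 52.1% of those listed, and 11855 genes reached it in every sample. The 3 samples gave close counts of 12092, 12107 and 12085 genes. At least 100 TPM was reached by 1845 genes, and the 129 genes at 1000 TPM or more held 31.5% of all TPM. Another 5789 genes were listed at 0 in all samples. Among genes of at least 5 TPM the median coefficient of variation over samples was 5.25%. Replicates 2 and 3 correlated at a Pearson r of 0.998 across 10143 genes on the log2(TPM + 1) scale, and replicate 1 correlated with them at 0.992 and 0.991. Genes are not independent replicates, so these correlations describe the libraries only.

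All 25 markers of T cell identity were at or above 1 TPM, with a median of 89.0 ± 7.54 TPM. Of the chains of the CD3 complex, through which the T-cell receptor signals, CD3D stood at 1432 ± 64.8 TPM, CD3E at 797 ± 14.3, CD3G at 326 ± 6.32 and CD247 at 194 ± 2.08. The receptor-proximal kinase LCK reached 767 ± 12.3 TPM and ZAP70 293 ± 17.8, and the adaptor LAT 177 ± 8.60. Transcription factors of the T lineage followed, with LEF1 at 599 ± 21.7 TPM, TCF7 at 393 ± 8.67, BCL11B at 50.2 ± 3.99 and GATA3 at 41.9 ± 1.43. Surface molecules covered a wider range. CD2 was at 269 ± 4.01 TPM, CD28 at 108 ± 5.71, CD7 at 89.0 ± 8.79, CD5 at 85.4 ± 1.18, CD6 at 36.8 ± 2.47 and CD96 at 33.5 ± 2.18. The coreceptor CD4 and the costimulatory receptor CD27 were lowest, at 9.31 ± 0.499 and 6.24 ± 0.893 TPM. SH2D1A at 195 ± 11.9 TPM, SIT1 at 85.7 ± 7.03, THEMIS at 54.1 ± 2.34, TRAT1 at 45.7 ± 2.46 and UBASH3A at 31.3 ± 0.473 were the other members named. The list median exceeded those of 10000 of 10000 random gene lists of the same size.

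Of 116 markers of other lineages in 9 lists, 25 were at or above 1 TPM (21.6%, 95% exact Clopper-Pearson interval 14.5 to 30.2). Among 7 of 19 cytotoxic and NK markers at that level, the protease granzyme A (GZMA) had 63.8 ± 2.37 TPM, NKG7 10.5 ± 0.304 and the chemokine CCL5 7.62 ± 0.869, while GZMB had 0.0288 ± 0.0498 TPM. B-cell markers were at or above 1 TPM in 5 of 15 cases, led by the B-cell receptor chain CD79A at 33.4 ± 3.44 TPM, the kinase BLK at 16.8 ± 0.984 and the coactivator POU2AF1 at 8.26 ± 0.119. PAX5 was at 0.0182 ± 0.0173 TPM. Myeloid markers reached 1 TPM in 4 of 18 cases, with CEBPE at 4.06 ± 0.510 TPM, CD68 at 3.63 ± 0.248 and LYZ at 3.06 ± 0.276. In the erythroid and megakaryocyte list, 2 of 15 did, EPOR at 5.45 ± 0.657 TPM and GP1BA at 2.85 ± 0.351. The epithelial list had 3 of 12, namely MUC1 at 3.63 ± 0.117 TPM, KRT8 at 3.43 ± 0.390 and KRT18 at 1.76 ± 0.513. THY1 at 31.2 ± 0.991 TPM was the only stromal marker of 12 above the floor, and COL1A1 was at 0.799 ± 0.0476 TPM. Of 8 endothelial markers, PECAM1, an adhesion molecule that leukocytes also carry, had 19.7 ± 1.05 TPM and EGFL7 3.25 ± 0.615. Neuronal markers gave 1 of 8, SNAP25 at 2.71 ± 0.191 TPM, and hepatocyte markers 0 of 9, with CYP3A4 highest at 0.250 ± 0.215 TPM. With a floor of 0.1 TPM 55 of these markers passed, and with a floor of 5 TPM 9 did.

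**Figure D1:**
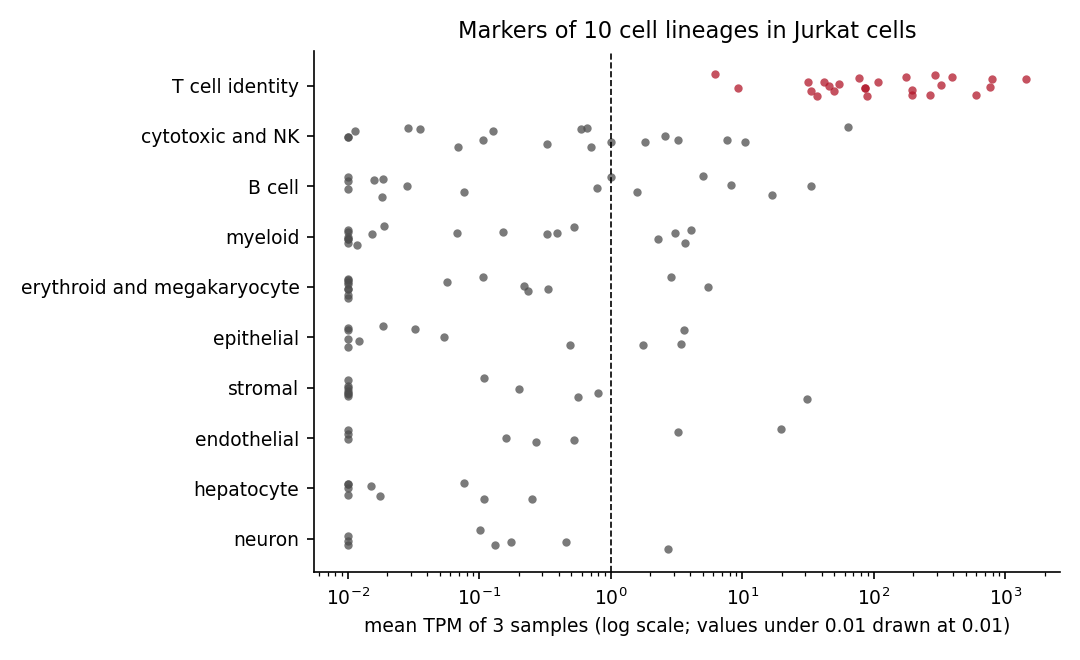
Mean TPM of 3 samples (log axis) for each member of 10 marker lists, 1 row per list and 1 point per gene; values under 0.01 are drawn at 0.01 and the dashed line marks 1 TPM. All 25 T cell identity genes lie between 6.24 and 1432 TPM, and 91 of the 116 other markers lie below the line.

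All 38 genes of the TCR signalling list, which carry or restrain the signal of the T-cell receptor, were at or above 1 TPM, with a median of 69.5 ± 2.54 TPM, above that of 10000 of 10000 random lists. LCK was the highest, followed by the phosphatase CD45 (PTPRC) at 322 ± 22.8 TPM and by ZAP70, and the lowest member had 5.75 TPM. The PI3K list also had all 20 members at that level. AKT1 had 148 ± 5.77 TPM, the regulatory subunit gene PIK3R1 65.0 ± 5.66 and MTOR 57.7 ± 1.62. Jurkat cells are known to lack the protein of INPP5D, a phosphatase that acts on the products of PI3K. Its messenger RNA was listed at 17.9 ± 0.630 TPM. The related INPPL1 had 23.5 ± 0.300 TPM. The PI3K median of 26.4 ± 1.1 TPM exceeded 9875 of 10000 random lists drawn from all genes, but only 9136 of 10000 when genes at 0 were left out of the background.

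Of 26 listed transcription factors linked to T-cell acute lymphoblastic leukaemia, 16 were at or above 1 TPM. MYB had 435 ± 22.8 TPM, MYC 282 ± 1.06, RUNX1 226 ± 13.2 and TAL1, a basic helix-loop-helix factor switched on in part of these leukaemias, 162 ± 6.94. The E proteins that pair with TAL1 were TCF12 at 209 ± 12.5 TPM and TCF3 at 122 ± 0.532 TPM. IKZF1 stood at 189.8 ± 10.6 TPM, ETV6 at 33.3 ± 1.55 and RUNX3 at 12.2 ± 0.760. In the Notch pathway, NOTCH1 had 28.2 ± 1.45 TPM and NOTCH3 16.7 ± 0.615, and the Notch targets DTX1 and HES1 had 54.3 ± 0.608 and 33.2 ± 1.34. Among the LIM-only factors, LMO1 was at 3.61 ± 0.359 TPM, LMO2 at 0.110 ± 0.0562 and LMO3 listed at 0. TAL2 had 0.987 ± 0.180 TPM and LYL1 0.0576 ± 0.0631. The homeobox genes were near 0: HOXA9 had 0.0298 ± 0.0516 TPM, NKX2-1 0.0268 ± 0.0241, TLX1 0.0166 ± 0.0287 and HOXA10 0.0128 ± 0.0221, with TLX3 listed at 0. MEF2C had 0.0159 ± 0.0143 TPM.

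**Figure D2:**
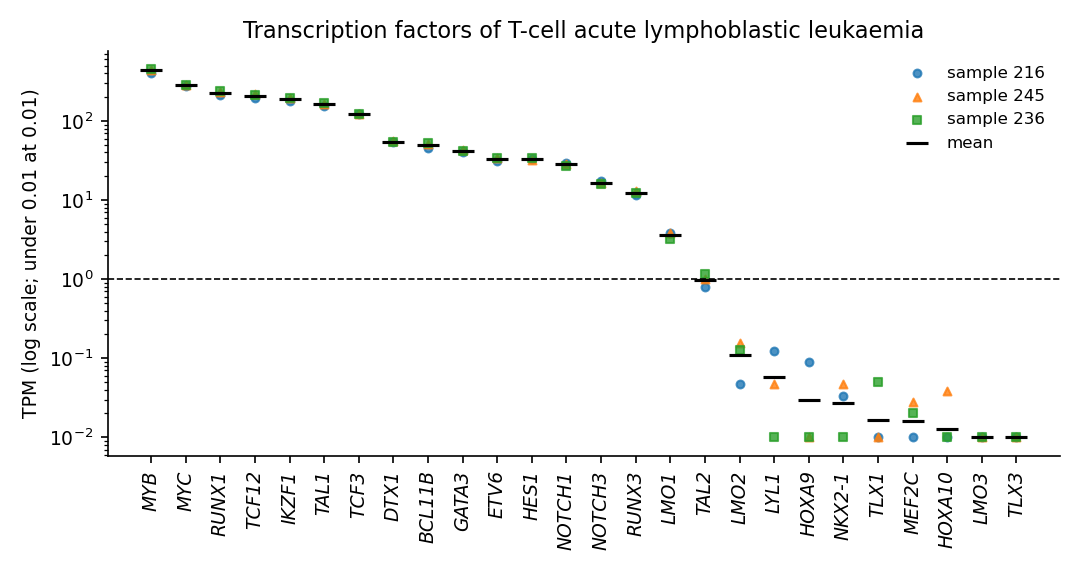
TPM (log axis) of 26 transcription factors linked to T-cell acute lymphoblastic leukaemia, with 1 symbol per sample and a bar for the mean of 3; values under 0.01 are drawn at 0.01 and the dashed line marks 1 TPM. The means of the 16 genes above the line run from 3.61 TPM for LMO1 to 435 TPM for MYB.

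The thymocyte and V(D)J recombination list had values for 17 of its 22 genes, all at or above 1 TPM. The Ku subunits XRCC6 and XRCC5, which bind DNA ends, had 1044 ± 31.9 and 813 ± 51.8 TPM. CD1E, a CD1 family gene of cortical thymocytes, had 903 ± 26.9 TPM. The other 5 members, receptor constant-region genes, had no TPM value in the table. Activation genes were mostly low: 6 of 25 reached 1 TPM. CD40LG had 46.4 ± 1.88 TPM, CD69 35.4 ± 0.666 and NR4A1 5.4 ± 0.636, while the high-affinity interleukin-2 receptor chain IL2RA had 0.0278 ± 0.0272 TPM and the chemokine IL8 0.0403 ± 0.0699. In the checkpoint and helper subset list 10 of 21 did. The chemokine receptor CXCR4 had 618 ± 21.2 TPM and CCR4 11.4 ± 0.539, against 0.0358 ± 0.0199 for MAF and 0.0109 ± 0.0188 for TIGIT.

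Cell cycle genes were at or above 1 TPM in 24 of 26 cases, with a median of 241 ± 3.05 TPM that exceeded 10000 of 10000 random lists. TYMS, which makes thymidylate, had 951 ± 28.8 TPM, the replication clamp PCNA 817 ± 22.5 and the kinase CDK6 601 ± 48.6. Both members below the floor were D-type cyclins, CCND2 at 0.564 ± 0.143 TPM and CCND1 at 0.215 ± 0.0792 TPM. The list of genome guardians and mismatch repair genes had 16 of 19 members at the floor, with RB1 at 309 ± 24.6 TPM and CHEK1 at 129 ± 6.2. The exceptions were MLH3 at 0.340 ± 0.00786 TPM and the cyclin-dependent kinase inhibitor genes CDKN2A and CDKN2B, both listed at 0 in all 3 samples. All 19 apoptosis genes were at or above 1 TPM, led by MCL1 at 124 ± 8.34 TPM, cytochrome c (CYCS) at 120.1 ± 9.15 and BCL2L1 at 100.3 ± 2.22.

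The cytosolic ribosomal proteins had the highest list median at 1809 ± 206 TPM, and 84 of 87 reached the floor. Proteasome genes had a median of 326 ± 3.32 TPM, with PSMA6 at 1023 ± 24.3, PSMA4 at 623 ± 21.8 and PSMB7 at 562 ± 15.7. Core spliceosome genes had a median of 280.5 ± 16.2 TPM, with SNRPD2 at 667 ± 37.2, SNRPB at 648 ± 33.2 and U2AF1 at 578 ± 14.1. All members of both lists were at or above 1 TPM. Among splicing regulators, 28 of 31 were. HNRNPA1 had 2975 ± 164 TPM, HNRNPA2B1 1503 ± 79.5 and HNRNPC 829 ± 35.8, whereas the epithelial regulator ESRP2 had 0.143 ± 0.0768 TPM and the neuronal regulators RBFOX1 and NOVA2 were listed at 0. Glycolysis genes had a median of 212 ± 1.26 TPM, with LDHB at 2744 ± 82.8 and ENO1 at 1985 ± 12.7 after GAPDH. Nuclear genes of oxidative phosphorylation had a median of 169 ± 8.92 TPM and 76 of 83 at the floor, with ATP5B at 1217 ± 29.5 and COX7C at 1203 ± 183. Mitochondrial ribosomal proteins had a median of 87.2 ± 1.81 TPM, led by MRPL20 at 347 ± 13.8. Nonsense mediated decay genes, which clear messages with early stop codons, all passed 1 TPM around a median of 57.5 ± 2.52, with SMG5 highest at 104 ± 1.77.

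All 8 genes of the MHC class I list were at or above 1 TPM, with B2M at 2217 ± 40.5, CALR at 1061 ± 20.3 and PDIA3 at 214 ± 9.95 TPM. In the class II list, the RFX factors were expressed, RFX5 at 90.1 ± 2.43 TPM, RFXANK at 52.1 ± 2.69 and RFXAP at 28.2 ± 1.21. The class II transactivator CIITA had 0.0511 ± 0.0205 TPM and the invariant chain CD74 0.186 ± 0.114. Replication-dependent histone genes, whose messages end without a poly(A) tail, reached 1 TPM in 11 of 72 cases, with HIST1H2BK highest at 9.75 ± 0.736 TPM. Of the 20 pathway lists, 16 had a median above those of 9500 of 10000 random lists. The random lists drew on all 23221 listed genes, 5789 of them at 0 in all samples. A high place of a pathway list thus shows expression above that background and nothing particular to these cells.

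The junction list is the second measurement and bears on which splice junctions these cells use. EEF1A1 held 7 of the 10 junctions with the most reads among those with a length match, all on the minus strand of chromosome 6 between 74227658 and 74230722 (hg19), the deepest with 91038 reads at the intron from 74228952 to 74229059. The others lay in GAPDH (43531 reads, chromosome 12, 6645760 to 6645849), RPS18 (41285 reads, chromosome 6, 33243661 to 33243741) and TMSB4X (39922 reads, chromosome X, 12994481 to 12994895). Over all 280884 junctions the median was 8 reads, with quartiles of 2 and 115. A single read supported 59350 junctions (21.1%, interval 21.0 to 21.3), while the 134675 junctions with at least 10 reads held 99.2% of all junction reads. Introns ranged from 12 to 499865 bases with a median of 1830. Intervals of shares here and below are 95% exact binomial intervals and cover counting error only.

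Whether a junction is known to an annotation was judged by length, because the annotation at hand, GENCODE release 29, is of GRCh38 and the junctions are of hg19. An annotated intron of the same chromosome, strand and length existed for 80.5% of junctions (80.4 to 80.7), against 57.7% when lengths were shifted by 1 to 10 bases. Short introns matched by chance almost always, so introns over 10000 bases are the informative class. Of 44008 such junctions, 48.4% matched (48.0 to 48.9) against 4.71% after shifting. The share was 19.8% for junctions with 1 read, 47.4% with 5 to 9 reads, 96.9% with at least 100 but fewer than 1000 reads and 95.9% (93.0 to 97.9) with 1000 reads or more. Matched junctions of this class had a median of 22 reads, with quartiles of 4 and 106, and unmatched ones a median of 2, with quartiles of 1 and 4. Among the 22695 long unmatched junctions, 37.8% had both ends in common with length-matched junctions of more reads, 40.0% had 1 such end and 22.2% had neither. Among the 2120 of them with at least 10 reads, these shares were 35.9%, 27.7% and 36.3%. The length-matched junctions here were of any length, and short ones match by chance, so a shared end need not be a known splice site. The unmatched junction with the most reads, 8721, was the intron from 42365282 to 42373100 on the plus strand of chromosome 19. The next lay on chromosome 22 from 29688596 to 29692228 with 3179 reads and on chromosome X from 64887721 to 64936679 with 3122 reads. An intron whose length differs between the builds also lacks a match, so unmatched does not mean unannotated.

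**Figure D3:**
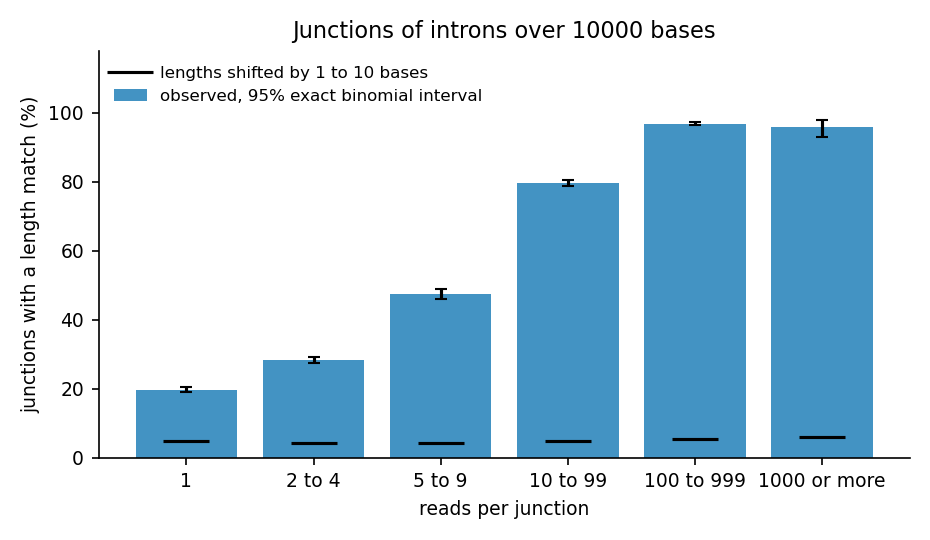
Percent of junctions of introns over 10000 bases that have an annotated intron of the same chromosome, strand and length (bars from 0, with 95% exact binomial intervals), by reads per junction; black marks give the percent after shifting lengths by 1 to 10 bases. The observed percent is 19.8 at 1 read and 96.9 in the class from 100 to under 1000 reads and 95.9 from 1000 reads, while the shifted percent stays between 4.18 and 6.16.

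Both files were also compared gene by gene, with junctions placed in 11820 genes by a match of intron, exon and intron lengths to annotated structures. Summed junction reads and TPM had a Spearman correlation of 0.882 across genes and a Pearson correlation of 0.894 on the log2 scale. The mean number of reads per junction, which does not grow with the number of introns, gave a Spearman correlation of 0.952. These are correlations across genes within 1 cell line, and no p-value is attached to them.

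Exon skipping was measured for 47305 exons with both inclusion junctions, a skipping junction and at least 20 reads in all. The median inclusion was 94.6%. Inclusion of at least 95% was seen for 48.8% of these exons (48.4 to 49.3), 20 to 80% for 11.8% (11.5 to 12.1) and under 5% for 15.4% (15.1 to 15.7). These are stretches inferred between junctions. The structure matched the annotation for 1482 of the 7279 under 5%, against 15862 of the 23107 at 95% or more. The 15.4% is thus not a share of annotated exons. With the smaller inclusion junction in place of the mean, the share at 20 to 80% was 24.9%. Exons included at 20 to 80% had lengths that are multiples of 3 in 41.5% of cases (40.2 to 42.8), against 38.0% (37.4 to 38.7) of exons included at 95% or more. With every spanning junction counted as skipping, these shares were 40.1% and 38.4%. In exons whose structure matched the annotation these shares were 48.4% (46.5 to 50.3) and 39.7% (38.9 to 40.5). The structure match named a gene for 25291 exons, and 0.0333% matched after an intron length was shifted.

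Of the 20 genes of the isoform list, 15 had cassette exons included at 5 to 95%, 26 exons in all. Overlapping forms of an exon are counted separately. These are the forms of 35 and 41 bases in LEF1 and of 129 and 150 bases in PICALM. Mutually exclusive exons are not part of this count. In PTPRC, the variable exons that set the CD45 isoform had inclusions of 9.08% (7.53 to 10.8) for the 198-base exon (chromosome 1, 198665841 to 198666038), 55.2% (52.8 to 57.5) for the 141-base exon (chromosome 1, 198668693 to 198668833) and 33.8% (31.1 to 36.6) for the 144-base exon (chromosome 1, 198671516 to 198671659). These values take the skipping junction with the most reads. Counting every spanning junction that shares an outer end gave 5.55% (4.59 to 6.64), 54.6% (52.2 to 56.9) and 20.3% (18.5 to 22.2), an alternative chosen after seeing the data. Reads that skip all 3 exons at once count against the 141-base exon in both measures and against the other exons only in the second. The second measure adds skipping reads only, so it cannot raise inclusion. Both measures use 1 inclusion junction on each side. For the 141-base exon they leave out 120 reads joining it to the 198-base exon and 341 joining it to the 144-base exon. This lowers its inclusion in both measures. TCF7 included a 93-base exon at 30.1% (27.7 to 32.5) and LEF1 an 84-base exon (chromosome 4, 109002742 to 109002825) at 74.4% (73.1 to 75.6). MALT1, a protease scaffold downstream of the T-cell receptor, included a 33-base exon at 31.5% (19.5 to 45.5), and MAP2K7 a 48-base exon at 28.6% (11.3 to 52.2), both with wide intervals from few reads. The splicing regulator MBNL1 included a 54-base exon (chromosome 3, 152164493 to 152164546) at 20% (17.4 to 22.8), and NUMA1 a 42-base exon at 20.8% (18.0 to 23.7). IKZF1 included a 126-base exon at 77.8% (74.6 to 80.7), LCK a 153-base exon at 92.3% (91.3 to 93.3) and CELF2 an 80-base exon at 89.7% (86.8 to 92.1). The 63-base exon of FAS that encodes the membrane-spanning part was included at 96.6% (92.2 to 98.9), and the 36-base exon of CD247 at 98.6% (97.6 to 99.2). CD44, at 0.0697 ± 0.0483 TPM, and BCL2L1, at 100.3 ± 2.22 TPM, gave no measurable exon. In 5 of the 26 exons, 1 inclusion junction had over 3 times the reads of the other.

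**Figure D4:**
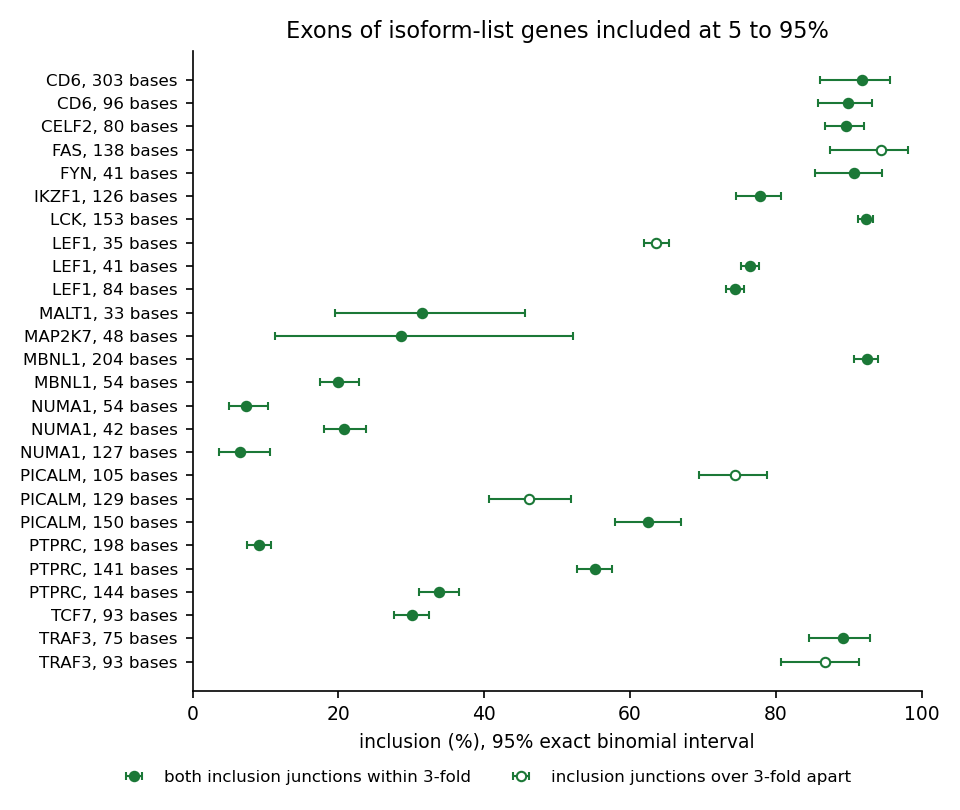
Inclusion (percent, horizontal axis from 0 to 100) of 26 exons of 15 isoform-list genes with inclusion of 5 to 95%, each labelled by gene and exon length, with 95% exact binomial intervals; open symbols mark 5 exons whose inclusion junctions differ by over 3-fold. The PTPRC exons of 198, 141 and 144 bases lie at 9.08, 55.2 and 33.8%, with only the skipping junction of most reads counted. The LEF1 exons of 35 and 41 bases overlap, as do the PICALM exons of 129 and 150 bases.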

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

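The junction list holds 410 junctions on the mitochondrial chromosome, whose genes have no introns. They are counted in the junction totals and the length match of the report, but no comparison there looked at them by themselves, which is why they are given here. They carry 2067 reads, with a median of 4 and a maximum of 60 at the gap from 9334 to 9394 on the minus strand, and make up 0.146% of all junctions. The tests below were chosen after the junctions were found and before the values they measure were seen. Splicing of transcripts of the heavy strand genes, which read along the plus strand, would put most reads on that strand. The junction list put 31.4% (29.4 to 33.5) there, which speaks against such splicing if the listed strand is that of the transcript. How the list assigned strands is not given in the sources used here. Repeated use of the same sites is undecided, since 17.4% (14.5 to 20.7) of mitochondrial splice sites were shared by several junctions, against 17.5% elsewhere, counting only junctions of at least 2 reads, and elsewhere of at most 60. No biological explanation other than this splicing was tested.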

How the results depend on the processing

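The number of detected genes stayed between 10143 and 14920 under all alternatives, and between 12092 and 12105 when each replicate was left out in turn (12096 in the report). All 25 T cell identity genes kept their side of every floor, and markers of other lineages numbered 24 to 25 with a replicate left out, 55 with a floor of 0.1 TPM and 9 with a floor of 5 TPM. Pathway lists above 9500 of 10000 random lists numbered 16, or 15 with genes at 0 left out of the background, and the number of pathway members at the floor stayed within 1.5 times its value throughout. Junctions fell to 161198 at 5 reads or more and 134675 at 10 or more, by construction, and 20.1% had 1 read where both overhangs reached 20 bases. The length-matched share was 85.4, 92.7 and 96.1% at 2, 5 and 10 reads or more, 74.2% with protein-coding introns only, 80.9% up to 100000 bases, 48.4% over 10000 bases (chosen after seeing the data) and 99.2% weighted by reads. The correlation of TPM with junction reads was 0.834 for genes at 1 TPM or more and 0.952 with mean reads per junction. Exons at 20 to 80% inclusion made up 8.91% with 50 reads or more, 24.9% with the smaller inclusion junction, and 10.3% among the 25992 with a matched structure, an alternative also chosen after seeing the data. With the smaller junction, inclusion of the 138-base exon of FAS fell below 50% to 28.6%, inclusion of the 35-base exon of LEF1 to 6.28% and inclusion of the 105-base exon of PICALM to 40.5%. The 35-base exon of LEF1 overlaps a 41-base exon and uses the same downstream junction, with 3835 reads. Its own upstream junction had 75 reads, against 3425 for the 41-base exon. Its value with the mean of both junctions thus rests on reads that the 41-base exon also uses. The cause of the other moves was not tested. Counting every spanning junction as skipping, also chosen after seeing the data, put 13.0% of exons at 20 to 80%; of 83 exons of isoform-list genes 78 stayed within their interval and 5 moved. Rescaling without the 10 highest genes multiplies all others by the same factor, so it changes no gene against another. No paired analysis was possible because there is 1 group. TPM keeps no depth, and the number of reads in the series text was not used, so what depth limits is unknown.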

Other observations

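Further thymocyte genes, named here after their values were seen, were expressed: DNTT, which adds bases at V(D)J joins, had 233 ± 10.6 TPM, the recombinase genes RAG2 and RAG1 14.1 ± 1.12 and 9.98 ± 0.811, CD1A 180.3 ± 8.57 and the pre-T-cell receptor chain PTCRA 3.15 ± 0.575 TPM. The junction list also held reads joining 7 of 14 measurable T-cell receptor beta J segments, TRBJ2-1 to TRBJ2-7, to TRBC2 at 142498724 on chromosome 7 (hg19), placed by intron lengths. TRBJ2-1 had 569 reads, TRBJ2-3 149, TRBJ2-4 42, TRBJ2-2 31 and the others 9 or fewer. The 14 counts every annotated beta J segment upstream of TRBC2. The search left out constant genes joined by only few segments at a shared end. Which receptor these cells use can therefore not be read from these values.

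Some neighbouring exons were used in place of each other, with few reads joining or skipping both; these genes were named after their values were seen. In PKM, listed as PKM2 at 1168 ± 17.1 TPM, the downstream 167-base exon (chromosome 15, 72494795 to 72494961), which marks the M2 form, held 90.6% (89.7 to 91.5) and the upstream one 9.37%, with 5 reads joining both. MAPK14 held 67.9% and 32.1%, RAB6A 59.8% and 40.2%, DNM2 55.9% and 44.1%, and MAPK9 97.7% and 2.32%. Acceptor sites within 50 bases of each other formed 4849 pairs, of which 30.2% (28.9 to 31.5) were 3 bases apart, with a median minor share of 15.0%. Among placed genes, CASC15 had the most long unmatched junctions of at least 5 reads, 21, followed by MIR646HG with 13, LDLRAD4 with 10 and CCDC26 with 9.

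Replicate 1 departs most from the other samples, and the GC test of this was chosen after the pattern was seen. Its departures had an SD of 0.2 on the log2 scale, against 0.123 and 0.134, with RPL21 at 32.1, 84.6 and 124.8 TPM in replicates 1, 2 and 3. In the 94.8% of genes with a known GC content the SDs were 0.13, 0.0822 and 0.112, and with the GC trend removed 0.103, 0.0779 and 0.099. Replicate 1 then hardly stood apart from replicate 3 in these genes. The larger part of its fall, from 0.2 to 0.13, came from leaving out genes without a known GC content. Only the fall from 0.13 to 0.103 came from removing the GC trend. Departures correlated with transcript GC content at a Spearman of 0.688 in replicate 1, -0.382 in replicate 2 and -0.578 in replicate 3, values that are tied because each sample is set against the others, and with transcript length, GC removed, at -0.209 in replicate 1, so both stay open. A different growth state is not borne out by the cell cycle genes. The median over 24 cell cycle genes of each gene's departure less that of its GC-matched genes was 0.00888 (-0.00928 to 0.0219). The difference of both medians, added after seeing the data, was 0.02 (-0.0227 to 0.051). Both intervals are 95% bootstrap intervals from 1000 resamplings of the 24 genes, not binomial ones. They treat the genes as independent and do not measure the spread between samples.

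Columns with the same C number deviate together across samples. Of 36 ways to line the columns up, 1, the real one, had a mean correlation as high as the 0.116 observed, a test written after the pattern was seen, so a source shared by those columns remains possible. In the genes with a known GC content the mean was 0.107, and removing each column's GC trend left 0.0701, against 0.0573 for the highest other way after the same removal, so GC alone does not account for it. Lining the columns up again after that removal was added after seeing the data. No biological explanation was tested, and what C01 to C03 stand for is not given in the sources used here.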
